A study of Mus musculus with 7 samples.

How the data were processed

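Gene expression was measured by RNA sequencing of liver from male C57BL/6J mice aged 6 months, in 3 wild-type and 4 homozygous Sprtn Y118C knock-in animals, per the labels. Sprtn encodes a protease that removes proteins crosslinked to DNA. Per the labels' protocols, RNA was extracted with Qiazol, polyadenylated RNA was enriched with oligo(dT) beads and fragmented, and cDNA was made with random hexamers. The second strand was made with ordinary dNTPs, per the labels' protocols, so that reads from genes that overlap on opposite strands were treated here as not separable. Reads were placed on the mouse build mm10, per the submitters' processing notes. The mapper, the counting program and the annotation release are not given in the sources used here.

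The gene counts are the total counts per gene and library that the authors deposited, per the file headers, as whole numbers without normalization. The authors also deposited a log2 fold change of knock-in over wild type and a p-value corrected by a false discovery rate, per the file headers, and the program behind them is not given in the sources used here. These other columns of the authors' table were used only to set the authors' calls beside the new ones. The RPKM, TPM and CPM columns of each library, 21 columns in all, were not used. The table held 51826 genes, of which 21027 had at least 1 count. Of the gene identifiers, 99.6% were found in GENCODE release M21, and 94.2% of these had the same position and strand there, so that coordinates are given on mm10 as the table gives them. Total counts ranged from 36928472 to 46755357 per library. No pair of libraries of the same genotype agreed within sampling noise in a chi-square test of their counts.

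Groups were taken from the labels, and each library was treated as 1 animal. Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default expression filter and the quasi-likelihood F test, with group as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Of 13989 genes tested, library-scaled CPM values are given as mean ± SD over libraries, and fold changes as knock-in minus wild type on the log2 scale with their standard error (SE). A set of 42 gene lists was fixed before the data were examined, and the 40 lists with at least 5 measured members were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01 on log2 CPM with a prior count of 2. Each list was also tested with an estimated correlation, with fry, and with an exact permutation test of its mean log2 CPM over the 35 splits of the libraries into 3 and 4. The score of a list in a library is the mean of its members' log2 CPM, each centred on its mean over the libraries. Called genes within 10 Mb of Sprtn were compared with those elsewhere by a Fisher exact test. The smallest two-sided p that an exact permutation test of 3 against 4 libraries can give is 0.0286.

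Genes were named by a rule fixed before the data were examined. It took called genes with a mean CPM of at least 1, no overlap between the groups and no clone or pseudogene name. Where fewer than 5 genes passed in a direction, the 5 with the smallest p were named, whether or not they passed. Sprtn and up to 4 members of each list with the smallest p were added. Not all of these genes are described in the text, and 1 of them is not reported here. Named after their values were seen were 2410089E03Rik, Gm7334, Meg3, Rian, Ddi2, Clec4f, Csf1r, Apoa4, Gm45526, Rab4a, Agt, Nrp1, Adipoq, Plin1, and the skeletal muscle genes found in 1 library. Overlap of the named genes with exons of other genes was taken from GENCODE release M21, with pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. A gene at 0 in a whole group was given a floor of 3 counts per library, and ratios of summed counts have exact 95% intervals. Intervals and floors cover counting error only.

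The alternatives fixed before the data were examined were the DESeq2 1.42.0 Wald test, limma-voom, RLE and upper-quartile scaling, no expression filter, a filter of CPM of at least 1 in at least 3 libraries, robust dispersion, a 2-fold threshold, the replicate number as a block, and leaving out each library. The edgeR likelihood ratio test, a zonation score as a covariate, and other sets of calls near Sprtn were added after the data were seen. The fits were tested on simulated counts of 13810 genes with 3 against 4 libraries and 200 changed genes. The quasi-likelihood test called 68.0% of the genes changed by 2-fold and 96.0% of those changed by 4-fold, and 18 of its 179 calls were false. DESeq2 made 211 calls in the same data, of which 45 were false, and the likelihood ratio test 211, of which 43 were false. Each simulated gene was drawn independently, with a dispersion estimated from the real libraries. The simulated counts therefore held no variation shared between genes, and the percentages recovered need not hold in the real data.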

Results

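Liver transcriptomes of 3 wild-type and 4 Sprtn Y118C homozygous knock-in male mice were compared at 6 months of age. Sprtn is a DNA-dependent metalloprotease that degrades proteins covalently trapped on DNA, and the series asks how its mutation alters gene expression in the liver. Total counts were 42879895, 40297676 and 46755357 in the wild-type libraries and 46736592, 36928472, 39396550 and 42760220 in the knock-in libraries. On the first principal component of log2 CPM, which held 29.5% of the variance, wild-type replicate 1 lay at -9.56, within the range of the knock-in libraries from -26.4 to -7.95, while the other wild-type libraries lay at 32.5 and 36.0. Knock-in replicate 1 also held skeletal muscle transcripts, with a summed 107 CPM of the muscle list against 2.23 to 3.94 CPM in the other 6 libraries.

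Sprtn mRNA itself was detected in every library of both genotypes. The gene (ENSMUSG00000031986, chromosome 8, 124897886 to 124906161, plus strand, mm10) had 10 ± 1.11 CPM in wild type (SD, n = 3) and 11.3 ± 0.946 CPM in the knock-in (SD, n = 4). The individual libraries gave 9.60, 11.3 and 9.15 CPM in wild type and 10.3, 11.9, 12.2 and 10.7 CPM in the knock-in. The log2 difference was 0.18 with an SE of 0.11 and did not pass (edgeR quasi-likelihood adjusted p = 0.589; exact two-sided permutation p = 0.143). A point mutation need not change the level of its transcript, so these values do not check the genotype labels. Of its exonic bases, 10.4% are shared with Gm45709 on the opposite strand.

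The comparison of all genes between genotypes showed a small set of large changes, led by targets of the tumour suppressor p53 and by a marker of liver-resident macrophages. Eda2r, a receptor of the tumour necrosis factor receptor family and a p53 target, rose 8.71-fold, from 0.720 ± 0.0514 CPM in wild type (SD, n = 3) to 6.30 ± 0.918 CPM in the knock-in (SD, n = 4). Phlda3, a p53-induced inhibitor of Akt signalling, rose 4.51-fold, from 1.08 ± 0.165 to 4.89 ± 0.767 CPM. Timd4, the phosphatidylserine receptor of resident Kupffer cells, fell 7.56-fold, from 5.72 ± 0.683 to 0.753 ± 0.156 CPM. Each of these genes had all 4 knock-in libraries on one side of all 3 wild-type libraries, as the naming rule required.

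The edgeR quasi-likelihood test called 5 of 13989 genes, 4 higher and 1 lower in the knock-in. Eda2r (ENSMUSG00000034457, chromosome X, 97333840 to 97377216) had a log2 change of 3.12 with an SE of 0.18 and an edgeR adjusted p of 7.17e-04. Phlda3 (ENSMUSG00000041801, chromosome 1, 135766119 to 135769136) had 2.17 with an SE of 0.19 and an edgeR adjusted p of 0.00813. Timd4 (ENSMUSG00000055546, chromosome 11, 46810800 to 46844332) had -2.92 with an SE of 0.20 and an edgeR adjusted p of 0.00132. Exoc4, a subunit of the exocyst that tethers secretory vesicles, rose by 0.91 on the log2 scale with an SE of 0.09, from 15 ± 1.01 to 28.3 ± 2.10 CPM (edgeR adjusted p = 0.0152). The clone-named gene 2410089E03Rik, chosen after its values were seen, rose by 1.65 with an SE of 0.19, from 6.02 ± 1.70 to 18.98 ± 2.02 CPM (edgeR adjusted p = 0.0490). In total 1478 genes had an unadjusted p under 0.05, 783 higher and 695 lower, where chance gives 699. Of the tested genes 10.9% had groups that did not overlap, where chance gives 5.71% for 3 against 4. DESeq2 called 144 genes higher and 78 lower, the 5 genes among them. The authors' deposited table held 133 genes at a corrected p under 0.05, 92 higher and 41 lower, again with the 5 genes among them. Its higher genes included 5 of the skeletal muscle list, Acta1, Ckm, Atp2a1, Tnni2 and Tnnt3. Their counts came almost only from knock-in replicate 1. The edgeR count was larger without wild-type replicate 1, when 64 genes were called higher and 34 lower. Leaving out wild-type replicate 2 left 2 genes higher and 2 lower, and leaving out knock-in replicate 1 or 4 left 2 higher. Without these libraries Exoc4 was not called (edgeR adjusted p = 0.139, 0.0937 and 0.0771), and 2410089E03Rik was called only without wild-type replicate 1 (edgeR adjusted p from 0.0525 to 0.197 without each other library). Eda2r, Phlda3 and Timd4 were called whichever library was left out.

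Further genes with the smallest p did not pass in the edgeR quasi-likelihood test. DESeq2 and the authors' deposited table did call Ccng1, Aen, Dsg1c, Slco1a4, Cxcl13 and Rsc1a1. Among those higher in the knock-in, Ccng1, which encodes cyclin G1, had a log2 difference of 0.72 with an SE of 0.09, and Aen, which encodes an apoptosis-enhancing nuclease, had 0.81 with an SE of 0.10 (edgeR adjusted p = 0.0592 for both). Among those lower, Dsg1c, a desmosomal cadherin, had -1.29 (edgeR adjusted p = 0.0725). Slco1a4, an organic anion transporter, had -0.90 (edgeR adjusted p = 0.0846), and Cxcl13, the chemokine that attracts B cells, had -2.76 (edgeR adjusted p = 0.101). Rsc1a1 had 227, 83 and 223 counts in the wild-type libraries and 0 counts in all 4 knock-in libraries, so that its mean CPM was at least 55.4-fold lower at a floor of 3 counts per library (edgeR adjusted p = 0.0554). Its single exon (chromosome 4, 141683851 to 141685599) lies on the same strand wholly inside an exon of Ddi2, in an annotated untranslated region. Ddi2 had 8859 to 11464 counts per library, and reads from Ddi2 and Rsc1a1 cannot be assigned with certainty. Whether both genotypes came from one colony is not given in the sources used here.

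**Figure D1:**
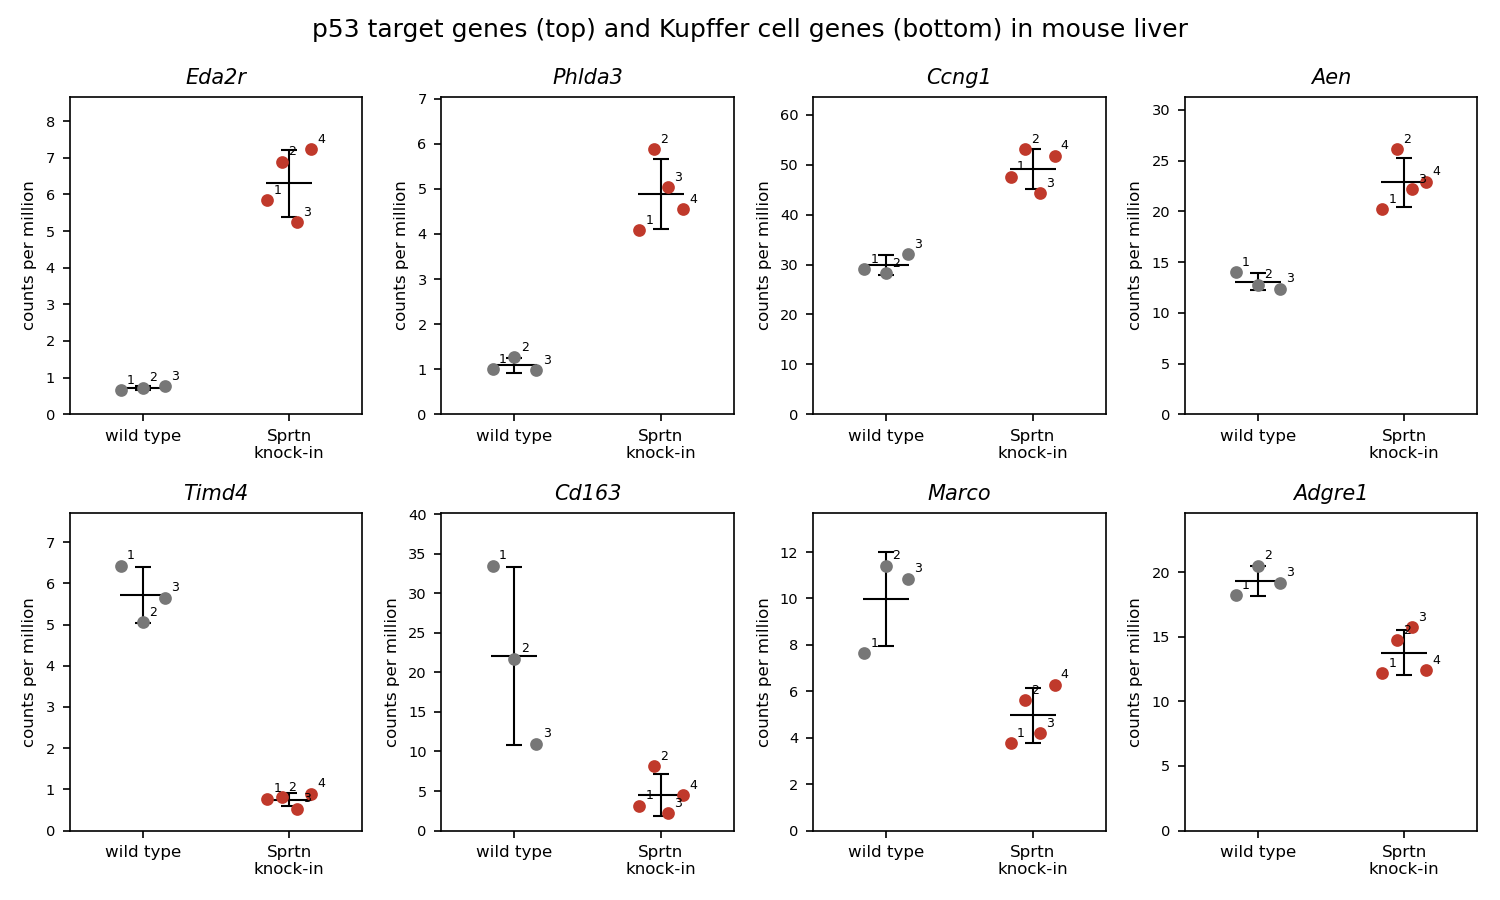
CPM of p53 target genes (top) and Kupffer cell genes (bottom) in each library, with the replicate number beside each point. Horizontal bars are group means and error bars are SD (3 wild-type and 4 knock-in libraries). The genes are the 4 members of each list with the smallest p, a choice that favours groups that do not overlap. The groups did not overlap for any of the 8 genes. Eda2r ranged from 5.25 to 7.23 CPM in the knock-in, and Timd4 from 0.532 to 0.895.

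The p53 target list was higher in the knock-in as a group. Of 27 measured members, 9 rose when adjusted over the list alone and 2 over all genes, none fell in either count, and 22 had positive log2 differences. The members with the smallest p were Eda2r, Phlda3, Ccng1 and Aen. Cdkn1a, which encodes the cell cycle inhibitor p21, had 7.60 ± 8.55 CPM in wild type and 20.5 ± 6.16 CPM in the knock-in and did not pass (edgeR adjusted p = 0.496), with 834 counts in wild-type replicate 3 against 57 and 164 in the other wild-type libraries. The list passed limma's camera test at the preset correlation (adjusted p = 7.54e-09) and limma's fry (adjusted p = 0.00269), but not camera with its correlation estimated from these libraries (adjusted p = 0.0831 with an estimated correlation). Its score was -0.37 ± 0.05 in wild type and 0.27 ± 0.09 in the knock-in, and the difference had an exact permutation p of 0.0286, the smallest that 35 splits can give, and 0.327 when adjusted over the 40 lists tested. At the preset correlation 9 lists passed in all, 5 higher and 4 lower, and with an estimated correlation 0 lists passed.

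Genes induced by interferon were mostly above wild type in the knock-in. Of 36 measured members, 35 had positive log2 differences, 16 rose when adjusted over the list alone, and 0 passed over all genes. Usp18, the protease that removes ISG15 from proteins, had 4.73 ± 0.816 CPM in wild type and 11.5 ± 3.49 in the knock-in. Ddx60 and Irgm1 had log2 differences of 0.72 and 0.51. DESeq2 called Usp18, Ddx60 and Irgm1 (DESeq2 adjusted p = 9.94e-05, 0.00343 and 0.0148). The list scores of knock-in replicates 1 and 3, 0.28 and 0.43, stood above those of replicates 2 and 4, -0.06 and 0.09, and wild type lay at -0.35 to -0.12. The list passed limma's camera test at the preset correlation (adjusted p = 4.13e-12), with an adjusted p = 0.704 with an estimated correlation. Limma's fry gave an adjusted p of 0.291, and the score difference had an exact permutation p of 0.0571 (0.327 adjusted over the lists). The list of nucleic acid sensors and the cGAS-STING pathway did not pass camera in limma (adjusted p = 0.538), and 0 of its 21 measured members passed over the list alone. Ifih1, a sensor of double-stranded RNA, had a log2 difference of 0.34. Antigen presentation genes did not pass camera in limma (adjusted p = 0.0826), and inflammatory cytokines and chemokines did not either (adjusted p = 0.327), although Cxcl13 fell when adjusted over the list alone.

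Hepatocyte genes of the 2 ends of the liver lobule differed in opposite directions. Pericentral genes, expressed around the central vein, had positive log2 differences in 19 of 20 members. Rhbg, an ammonium transporter, Slc13a3, Slc22a3 and Glul, which encodes glutamine synthetase, rose when adjusted over the list alone, with log2 changes of 1.67, 1.00, 1.08 and 0.72. Of the exonic bases of Rhbg, 61.4% are shared with Gm38392 on the same strand, which makes its counts uncertain. Periportal genes had negative log2 differences in 18 of 20 members, and 5 fell over the list alone, including Sdsl (-1.15), the serine dehydratase Sds (-0.91), the glutaminase Gls2 (-0.84) and Hsd17b13 (-0.44), and Sds shares 21.25% of its exonic bases with Plbd2 on the opposite strand. Apoa4, chosen after its values were seen, rose over the list alone by 0.93. In the edgeR quasi-likelihood test over all genes 0 members of either list passed. Over all genes DESeq2 called 4 pericentral genes higher and 4 periportal genes lower. The authors' deposited table held 2 pericentral genes higher, and 1 periportal gene higher and 3 lower, at its corrected threshold. Both passed limma's camera test at the preset correlation (adjusted p = 9.94e-07 pericentral and 4.14e-05 periportal), with an adjusted p = 0.751 and 0.704 with an estimated correlation. Exact permutation p values of the scores were 0.114 and 0.0286, or 0.457 and 0.327 when adjusted over the lists. Wild-type replicate 1 had a pericentral score of 0.24, within the knock-in range of 0.11 to 0.36, while the other wild-type libraries had -0.52 and -0.60. Its periportal score of -0.0134 lay just above the highest knock-in score, -0.0190 in replicate 3, while the other wild-type libraries had 0.41 and 0.18.

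**Figure D2:**
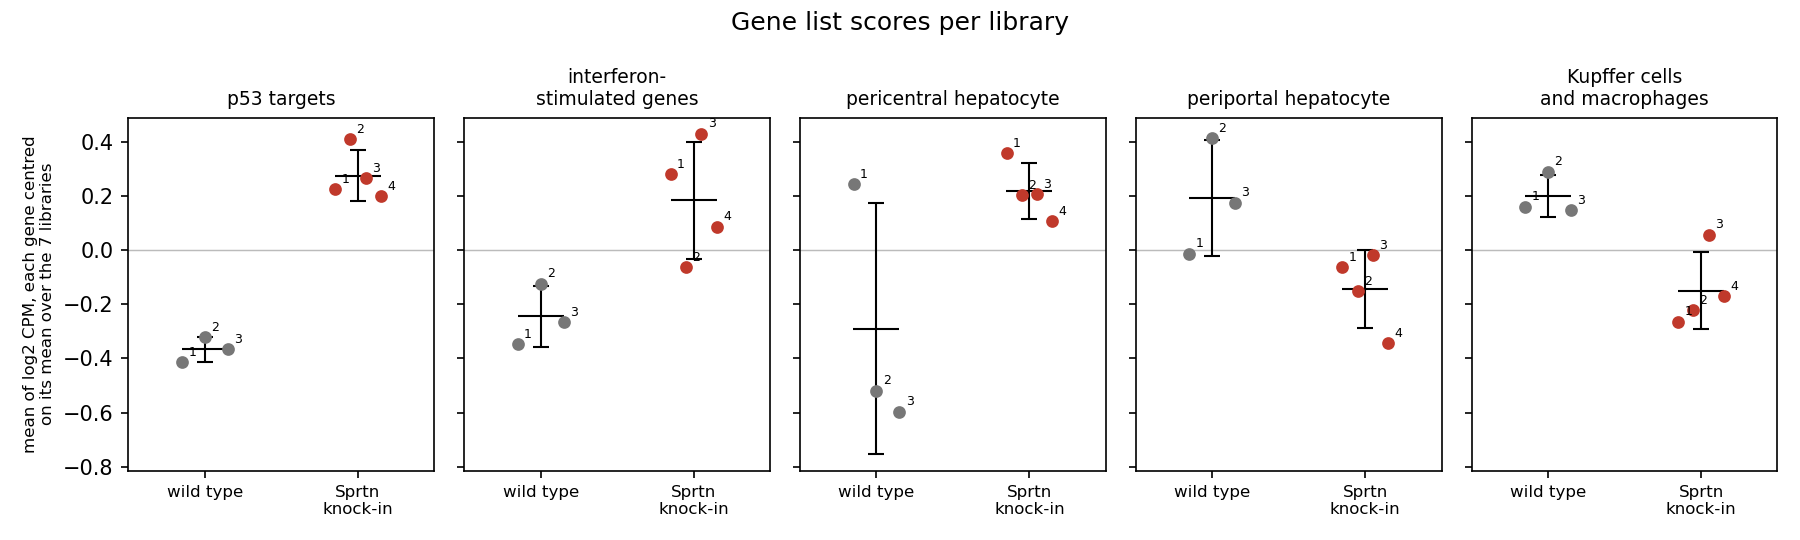
Score of 5 gene lists in each library, as the mean log2 CPM of the members after centring each gene on its mean over the 7 libraries; bars are group means and error bars SD (3 wild-type and 4 knock-in libraries), and numbers are replicates. The p53 target scores of wild type, from -0.41 to -0.32, lay below all knock-in scores, from 0.20 to 0.41, while the pericentral score of wild-type replicate 1 lay among those of the knock-in.

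Most genes of resident macrophages were lower in the knock-in. Of 23 members of the Kupffer cell and macrophage list, 16 had negative and 7 positive log2 differences. In edgeR 6 fell when adjusted over the list alone and 1, Timd4, over all genes. The others were the haemoglobin scavenger receptor Cd163 (-2.30), the scavenger receptor Marco (-1.01), Adgre1, which encodes the F4/80 antigen (-0.49), and, chosen after their values were seen, Clec4f (-0.49) and Csf1r (-0.63). Cd163 varied among wild-type libraries, at 22.1 ± 11.3 CPM against 4.48 ± 2.63 in the knock-in. The list passed limma's camera test at the preset correlation (adjusted p = 9.16e-05), with an adjusted p = 0.704 with an estimated correlation. In limma's fry it did not pass as a shift in one direction (adjusted p = 0.291), but passed as a mixture of directions (adjusted p = 6.37e-05). Other lists passed fry as a mixture too (adjusted p from 6.37e-05 to 0.0434). They were the p53, interferon, oncofetal, NRF2, lipogenesis, bile acid, male-biased, periportal and adipose lists.

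Markers of other cell types showed no list that passed limma's camera test. The adjusted p was 0.947 for T and NK cells, 0.327 for B and plasma cells, 0.284 for neutrophils, 0.327 for stellate cells and fibrosis, 0.627 for sinusoidal endothelial cells, 0.0828 for cholangiocytes, 0.327 for erythroid cells and 0.854 for adipose tissue and mesothelium. Spp1, which encodes osteopontin and stands in the cholangiocyte list, rose by 0.78 on the log2 scale when adjusted over that list alone, and shares 18.75% of its exonic bases with Gm42793 on the same strand. The pancreatic acinar and skeletal muscle lists had 2 measured members each and were not tested. In knock-in replicate 1 the muscle genes Ckm, Acta1 and Tnnt3 had 589, 912 and 612 counts, against 0 to 10 in the other libraries.

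Further lists that passed at the preset correlation held oxidative stress, male-biased and housekeeping genes. Of the targets of the oxidative stress regulator NRF2, 17 of 21 had positive log2 differences, and the carboxylesterase Ces2g (0.74) and the glutathione transferase Gstm2 (0.69) rose over the list alone. The list passed limma's camera test at the preset correlation (adjusted p = 0.00174; adjusted p = 0.704 with an estimated correlation). Gstm2 belongs to a family of similar genes, so its counts are uncertain. Among 25 male-biased liver genes, Cyp4a12a, an arachidonic acid hydroxylase, rose over the list alone by 0.78, and the list passed limma's camera test (adjusted p = 0.00179; adjusted p = 0.751 with an estimated correlation). The scores of knock-in replicates 1 and 3, 0.50 and 0.65, stood apart from those of replicates 2 and 4, -0.23 and -0.005, and from -0.31 to -0.30 in wild type, and without knock-in replicate 3 the adjusted p was 0.0499. Cyp4a12a and the major urinary protein genes of this list have near-identical copies, which makes their counts uncertain. Among female-biased genes Cyp2b10, Cyp17a1 and Abcd2 fell over the list alone by 1.14, 2.17 and 1.70 on the log2 scale, and the list did not pass limma's camera test (adjusted p = 0.627). Cytosolic ribosomal proteins had a median log2 difference of -0.17, with 32 of 34 members below 0, and nuclear-encoded oxidative phosphorylation genes had -0.13, with 27 of 31 below 0. Both passed limma's camera test (adjusted p = 4.57e-07 and 9.16e-05), with an adjusted p = 0.827 for each with an estimated correlation, and 0 members of either passed over the list alone. Rps6 and Cox7a2 had log2 differences of -0.27 and -0.35. In the edgeR quasi-likelihood test over all genes 0 members of the lists in this paragraph passed. DESeq2 called 2 NRF2 targets and 1 male-biased gene higher and 1 female-biased gene lower over all genes. The authors' deposited table held 2 NRF2 targets and 2 male-biased genes higher and 3 female-biased genes lower. Both called 0 genes of the ribosomal and oxidative phosphorylation lists.

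**Figure D3:**
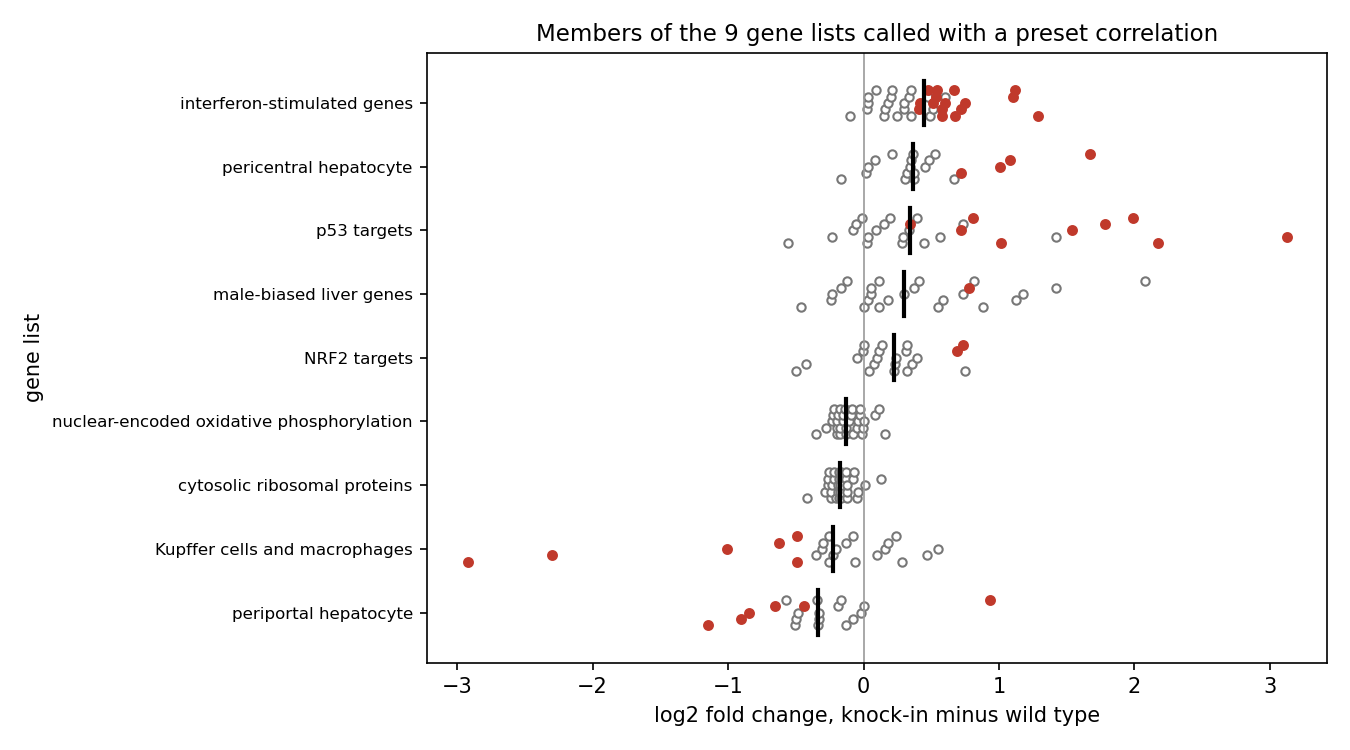
Log2 fold change of each measured member of the 9 lists that passed limma's camera test at the preset correlation, 1 point per gene. Filled red points passed when adjusted over the list alone, open points did not, and black bars are list medians. Of the 9 lists, 0 passed with an estimated correlation.

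Lipid and bile acid metabolism showed changes in a few genes and no list that passed limma's camera test. As a mixture of directions in limma's fry, the lipogenesis and bile acid lists passed (adjusted p = 0.00304 and 0.0315). In the lipogenesis list (limma's camera adjusted p = 0.538), Cidea, a lipid droplet protein, had 2, 0 and 1 counts in wild type and 83, 155, 56 and 43 in the knock-in, and rose over the list alone. The ratio of summed counts scaled by library was 88.4, with an exact 95% interval from 29.99 to 431, and the gene did not pass over all genes (edgeR adjusted p = 0.0592). Pparg rose over the list alone by 0.61. Cfd, which encodes the complement protease adipsin and stands in the adipose list, rose over that list alone, with a ratio of 25.9 and an interval from 12.4 to 65.0 (edgeR adjusted p = 0.0846 over all genes). Over all genes DESeq2 called both Cidea and Cfd (adjusted p = 3.91e-08 and 8.17e-08), as did the authors' deposited table (corrected p = 1.42e-08 and 1.975e-08) and edgeR without an expression filter (adjusted p = 0.0107 and 0.0305). Cidea was also called by edgeR without wild-type replicate 1 (adjusted p = 0.0391) and without knock-in replicate 2 (adjusted p = 0.0441). No other fit that left out 1 library called Cidea, and none called Cfd. Limma-voom called neither gene (adjusted p = 0.178 for Cidea and 0.210 for Cfd). Slco1a4 fell over the bile acid list alone and Sds over the gluconeogenesis list alone. Camera in limma gave adjusted p values of 0.687 for cholesterol biosynthesis, 0.830 for PPAR-alpha and fatty acid oxidation, 0.718 for bile acid metabolism, 0.659 for gluconeogenesis and 0.327 for xenobiotic metabolism.

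Genes of DNA repair and the cell cycle gave no list that passed limma's camera test. DNA-protein crosslink repair genes, to which Sprtn belongs, had an adjusted p of 0.830 in limma's camera test, with 0 of 20 members past the threshold over the list alone. For homologous recombination and Fanconi anaemia, DNA replication, and mitosis and proliferation, limma's camera gave adjusted p values of 0.327, 0.327 and 0.576. The proliferation marker Mki67 had 1.02 ± 0.166 CPM in wild type and 1.41 ± 0.532 in the knock-in. Senescence genes had an adjusted p of 0.995 in limma's camera test. Oncofetal and hepatocarcinoma genes had 0.108, with Ly6d, Spp1 and Lcn2, which encodes lipocalin 2, rising over the list alone by 1.73, 0.78 and 1.76. In the same limma test the adjusted p was 0.547 for acute phase genes, 0.243 for the unfolded protein response, 0.948 for the integrated stress response, 0.995 for the heat shock response, 0.729 for the circadian clock, 0.947 for immediate early genes and 0.995 for mitochondrially encoded genes. Among the lists that did not pass, the median, the mean and the direction of the test differed in sign for 10, namely nucleic acid sensing, senescence, acute phase, integrated stress, heat shock, PPAR-alpha, circadian clock, female-biased, mitochondrially encoded and adipose genes.

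No gene called by the edgeR quasi-likelihood test of all 7 libraries lay near the mutated locus. Within 10 Mb of Sprtn on chromosome 8, 0 of 123 tested genes were called by this test, against 5 elsewhere (Fisher exact two-sided p = 1). With so few calls, this comparison could hardly have shown an excess near Sprtn. At an unadjusted p under 0.05, 8.94% of the genes in this window and 10.6% of those elsewhere passed (Fisher exact p = 0.659). DESeq2 called 3 genes in the window, Gm45526, Rab4a and Agt (Fisher exact p = 0.449), and the authors' deposited table held 1 at its corrected threshold, Nrp1. These 4 genes were chosen after their values were seen.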

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

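The tests of Kupffer genes, of the label and depth of wild-type replicate 1, of the splits without it and of adipose tissue were chosen after the results were seen. The zonation covariate was also added after the data were seen, with its bound set before its value was known, and the test of single knock-in libraries for Cidea and Cfd was set before.

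In the knock-in group, 10 of 207 sets of 4 values had a library whose gap to the nearest of the others was larger, relative to their range, than Dixon's 95% critical value, where chance gives about 10. In knock-in replicate 3, Il1b stood apart at 3.37 CPM (others 1.08 to 1.24) and Cfd at 0.583 CPM (others 1.495 to 1.765). In knock-in replicate 4, Mcm6 was at 5.81 CPM (others 4.02 to 4.11), Ddx58 at 17.7 CPM (others 20.9 to 21.6) and Rpa2 at 4.71 CPM (others 5.17 to 5.22), and the circadian clock score was -0.25 (others 0.14 to 0.18). In knock-in replicate 2, Mcm2 was at 5.51 CPM (others 3.354 to 3.601), Cdkn1c, with 30.7% of its exonic bases shared with Gm44732 on the opposite strand, at 1.89 CPM (others 1.08 to 1.17) and Wfdc21 at 349.9 CPM (others 469.3 to 490.4). Mylpf, a muscle myosin light chain, was at 7.77 CPM in knock-in replicate 1 (others 0.393 to 0.565), the library that held the other muscle transcripts.

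More genes passed in edgeR when wild-type replicate 1 was left out, 98 in place of 5. In the 15 splits of the remaining 6 libraries into 2 and 4, the real split gave 98 genes and the highest other gave 1, and 15 splits are too few for a share under 0.05. The p53 target score of wild-type replicate 1 lay 0.61 (log2) below the lowest knock-in library. This score was picked after it had separated the groups with that library counted as wild type. It therefore cannot decide whether the genotype label of wild-type replicate 1 is wrong. A low depth of wild-type replicate 1 is argued against by its 42879895 counts, between those of the other wild-type libraries. With the pericentral minus periportal score as a covariate, all 7 libraries gave 4 genes, a number set in advance as counting against zonation as the source, but that bound was judged wrong by design once its value had been seen. The score of wild-type replicate 1, -1.91, lay within the knock-in range of -1.94 to -1.72, so that the covariate also takes up what separates the other wild-type libraries from the knock-in; a difference in zonation within wild type may therefore underlie these calls and cannot be told apart from an effect of genotype.

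Most Kupffer cell genes were lower in the knock-in, with 16 of the 23 listed members below 0 and 7 above. Fewer Kupffer cells and lower expression per cell cannot be told apart in whole tissue, since both predict that the other resident markers are below 0, as were all 12 of a set chosen after the values were seen. Timd4 lay -0.62 (log2, SE 0.51) from the lowest of these, Cd163 at -2.30. A smaller share of all non-parenchymal cells would lower the endothelial and stellate lists as well. Their median log2 differences were -0.0108 and 0.116, against -0.223 for the Kupffer list, so neither fell as the Kupffer list did. They lay 0.21 and 0.34 (log2) above it (permutation p = 0.0410 and 0.0138), more than the SDs of 0.175 and 0.301 among their own members. These permutation p values came from 100000 resamples and not from splits of the libraries, so they do not measure the variation between animals. Both gaps were less than the SD of 0.80 among members of the Kupffer list, so this explanation is not excluded. A loss of Timd4-positive resident macrophages, or of Timd4 expression in them, with the Sprtn mutation may be taken as a hypothesis, which counts of Timd4-positive Kupffer cells in stained liver would test.

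Cidea and Cfd were higher in the knock-in at low counts. Attached adipose tissue is argued against by the adipocyte genes Adipoq and Plin1, whose summed level differed by -0.0244 CPM from wild type to knock-in. Without any 1 knock-in library, both log2 changes kept at least 91.5% of their value, which argues against a single library as the source. An effect of genotype on Cidea and Cfd may remain as a hypothesis, which quantitative PCR in further animals would test. Over all genes neither passed in the edgeR quasi-likelihood test of all 7 libraries with the expression filter, nor in limma-voom. Both passed without the filter, in the edgeR likelihood ratio test and in DESeq2.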

How the results depend on the processing

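The numbers of genes higher and lower, 4 and 1 in the edgeR quasi-likelihood test, were 144 and 78 with DESeq2, 119 and 58 with the likelihood ratio test, 13 and 5 without an expression filter, and 2 and 2 with the zonation covariate, the likelihood ratio test and the covariate being added after the data were seen. With limma-voom 2 were lower. Scaling, the stricter filter, robust dispersion and the 2-fold threshold left 3 or 4 higher and 1 lower. Leaving out 1 library gave 2 to 64 higher and 1 to 34 lower, the highest without wild-type replicate 1, and 2 higher and 2 lower without wild-type replicate 2. Lists passing numbered 5 higher and 4 lower with camera, but 0 and 0 with an estimated correlation and 1 and 0 with fry, and 5 to 11 higher when 1 library was left out, 8 without wild-type replicate 2 and 11 without wild-type replicate 3. Without knock-in replicate 2 the PPAR-alpha list had a median of -0.0517 in place of 0.0491 and passed as lower (limma camera adjusted p = 0.0272); over all leave-one-out fits its median ran from -0.0517 to 0.112. Near Sprtn, 3 DESeq2 calls and 1 authors' call stood in place of 0. Except where fewer libraries or genes were used, the cause was not tested. The genes picked by the naming rule, together with 2410089E03Rik, which was chosen after its values were seen, kept their side of the threshold in 2446 of their alternatives, gained a call in 89 and lost it in 15. In the simulated data DESeq2 and the likelihood ratio test made more false calls than the quasi-likelihood test. Their calls there, 211 for each against 179, were far closer than in the real data. The simulation therefore does not explain the difference between the tests. At these depths, genes near 0.1 CPM rest on few counts.

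With the replicate number as a block, 1 gene was higher (Eda2r) and 0 lower, and knock-in replicate 4 had no partner. Same-numbered libraries did not deviate together (correlations across genes of -0.06, 0.01 and -0.02), which gave no sign that the numbers pair the animals. Libraries of unlike number had correlations from -0.24 to 0.26, so this check cannot exclude a pairing.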

Other observations

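Transcripts of the imprinted Dlk1-Dio3 region on chromosome 12, chosen after their values were seen, were among the genes with separate groups. Rian had 2.19 ± 1.05 CPM in wild type and 9.24 ± 3.15 CPM in the knock-in (edgeR adjusted p = 0.171; DESeq2 adjusted p = 3.74e-06), and Meg3 had 2.97 ± 1.89 and 8.001 ± 2.31 CPM (edgeR adjusted p = 0.290). Neither passed in edgeR.

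Genes at 0 in every library of 1 group and at 10 counts or more in every library of the other numbered 2, Rsc1a1 and the processed pseudogene Gm7334. Gm7334 had 0 counts in wild type and 51, 21, 21 and 17 in the knock-in, at least 9.37-fold higher at a floor of 3 counts per library. A strain or colony difference and, for Rsc1a1, the counting of reads shared with Ddi2 were not tested as sources of these counts. Other splits of the libraries gave at most 2 such genes, and 6 of them gave at least 1.

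The tests of chance for the number of genes and of lists were set before the results were seen, and that for the p53 list after. Of the 35 splits of the 7 libraries into 3 and 4, only the real one gave 5 genes in edgeR, the highest other giving 3. This argues against chance for that count. It does not exclude chance, since 1 split of 35 is the smallest share that these splits can give. The p53 target list differed by 0.64 (log2) in the real split and by 0.53 in size in the highest other (1 split of 35). Over the 40 lists tested its adjusted permutation p was 0.327. With a smallest permutation p of 0.0286, a single list could not fall under 0.05 after that adjustment. The adjusted value therefore cannot decide the question, and chance cannot be excluded for the p53 list by this test. For the number of lists passing limma's camera test at the preset correlation, chance cannot be excluded, since 29 of the 35 splits gave 9 lists or more, up to 20 in the highest other split.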
